A study of Parasynechococcus marenigrum WH 8102 with 9 samples.

How the data were processed

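The data are RNA sequencing of 9 libraries of Synechococcus WH8102, 3 biological replicates each at 36, 5 and 1 µM phosphate (High-P, Mid-P and Low-P). The deposited signal is a table of normalized read counts per gene, in which the authors divided each library's counts by its DESeq2 size factor, per the file headers and the values. Within each library every value was a whole multiple of 1 step (tolerance 0.0001), so whole reads were recovered for 100% of values. The submitters' processing notes name FastQC, Trimmomatic, Bowtie2, featureCounts and DESeq2, and their versions and the genome build are not given in the sources used here. The authors also deposited a comparison table of 2712 genes with log2 fold changes between treatments and log2-like group means, per the file headers. Its p-value columns hold adjusted values that the authors deposited as Benjamini-Hochberg adjusted p-values, per the file headers.

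Library names carry the prefixes 1, 2 and 3, one for each treatment, so if the prefixes mark sequencing runs, run and treatment cannot be told apart. The count table held 2718 entries, of which 6 were ERCC spike-in sequences, left out of all tests, that made up at most 0.000704% of the reads of a library. Of the 2712 genes 598 carried a gene symbol and 53 had no product description. No genome or coordinates were used, so gene positions are not described and neighbouring locus tags are named only as such.

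Depth ranged from 676862 reads in High-P B to 11846974 in Mid-P A. In High-P B 1 read equals 8.71 normalized reads, against 0.469 to 1.54 in the others. Normalized totals, in megareads, were 6.59 ± 0.697 in High-P, 8.41 ± 0.0827 in Mid-P and 5.27 ± 0.146 in Low-P (mean ± SD, n = 3 each). Spearman correlations between libraries of a group were 0.986 to 0.993 in Mid-P, 0.981 to 0.986 in Low-P and 0.859 to 0.938 in High-P. A count of 0 was taken to allow up to 3 reads.

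Genes with a mean of at least 10 normalized reads (2684 genes) were tested with limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with all 9 libraries in 1 fit (residual degrees of freedom 6), a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. Standard errors are those of limma. The 3 pairwise comparisons and an F test across the levels were made. Recovered reads were also tested with edgeR 4.0.16 and DESeq2 1.42.0.

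Gene lists were built from gene symbols and product descriptions. They were phosphate uptake, phosphate regulation, organic phosphorus hydrolysis, phosphonate and phosphite use, polyphosphate turnover, sulfolipid and glycolipid synthesis, phospholipid synthesis, arsenic and chromate, porins, phycobilisome, photosystem I, photosystem II, carbon fixation, ATP synthase, ribosomal proteins, nitrogen acquisition, chaperones and proteases, high-light inducible proteins, iron, oxidative stress, sigma factors, circadian clock, zinc, swimming motility and cell surface, tRNA synthetases, cell division and replication, and stable RNA. The 22 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. Patterns took in a few genes of other function. The ribosomal list holds modifying enzymes such as prmA, the cell division list shares ftsH genes with the chaperone list, and the phosphate regulation pattern caught phosphoribosyl enzymes. Locus tags of the older SYNW form matched 0 genes.

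Genes named in the text follow a rule. It takes the 10 largest rises and 10 largest falls between Low-P and High-P and the 5 largest of each in the other comparisons, among genes with an adjusted p under 0.05, a mean of at least 50 and no overlap between the groups. It adds up to 3 genes with the smallest p per list and all members of the phosphate uptake and organic phosphorus lists.

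The tests were tried on simulated counts with the real depths and, for each gene, 1 spread per group estimated from its 3 libraries. Simulated High-P A and C thus carried a spread estimated with High-P B, also in the fit without that library. The real median SD in High-P was 0.61 with High-P B and 0.34 without it. In Low-P versus High-P 16 of 99 genes changed 2-fold and 77 of 100 changed 4-fold were found, with 49 of 2479 unchanged genes called. In Mid-P versus High-P the values were 20 of 100, 59 of 100 and 49 of 2479, and in Low-P versus Mid-P 13 of 100, 65 of 100 and 0 of 2478. In these simulations false calls in both comparisons with High-P exceeded what the threshold allows. Their share of the calls depends on how many changed genes were put in, so it is not the share among the real calls. Alternatives covered pseudocounts, filters, scaling to equal library medians or equal totals, array weights, fits of 2 groups, a replicate block and fits without each library.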

Results

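Synechococcus WH8102 is an open-ocean picocyanobacterium, and the study grew it in exponentially fed-batch cultures, in which fresh medium is supplied at a rate matched to growth, at 3 phosphate levels. RNA was taken at the end of the experiment and sequenced after removal of ribosomal RNA. The groups were High-P (36 µM phosphate), Mid-P (5 µM) and Low-P (1 µM), each with 3 libraries named A, B and C that the labels describe as biological replicates. The deposited table held 2712 genes. Library depth differed between groups, with 10406707 to 11846974 reads assigned to genes in the Mid-P libraries and 10796699 to 11474863 in the Low-P libraries, against 4271264, 676862 and 5256432 in High-P A, B and C. In High-P B 671 genes (24.7%) had a count of 0, against 45 in High-P A, 33 in High-P C and 0 to 8 in the other libraries. A count of 0 in High-P B allows up to 26.1 normalized reads, against 4.63 or fewer in the others, and these limits cover counting error only. The median SD of a gene's log2 value was 0.61 in High-P, 0.17 in Mid-P and 0.18 in Low-P (n = 3 each), and 0.34 in High-P without library B. The comparisons, 27 gene lists and the rules for naming genes were chosen before the data were examined. Further lists, among them the heat shock genes, were chosen after the data were seen and are described separately.

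The Low-P and High-P cultures were compared to find the transcripts that differ between phosphate-poor and phosphate-rich growth. Of 7 phosphate uptake genes, 4 rose in Low-P and none fell. The gene pstS (TX72_RS12645), which encodes a periplasmic phosphate-binding protein, averaged 21.6 ± 19.7 normalized reads in High-P and 728 ± 249 in Low-P (mean ± SD, n = 3 each), a log2 fold change of 6.08 ± 1.29 (SE; adjusted p = 0.0104, limma). The transporter genes pstA and pstB rose by log2 fold changes of 2.17 ± 0.29 and 1.96 ± 0.50, and another pstS gene (TX72_RS05075) by 1.30 ± 0.31, from 3792 ± 1698 to 8842 ± 1432 normalized reads. Of the 5 genes for hydrolysis of organic phosphorus, 2 rose. They were a gene for a protein with a 5'-nucleotidase C-terminal domain (TX72_RS14590), from 80.6 ± 92.5 to 4164 ± 197 normalized reads (log2 fold change 7.54 ± 1.61, adjusted p = 0.0110), and an alkaline phosphatase D family gene (TX72_RS12775), from 110 ± 103 to 3190 ± 1002 (6.69 ± 1.74, adjusted p = 0.0237).

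Members that missed the threshold were pstC (log2 fold change 5.30 ± 1.92, adjusted p = 0.0756), a PstS family gene (TX72_RS06460, 0.76 ± 0.38) and the pstS gene TX72_RS09135 (-0.46 ± 0.17). The gene for the alkaline phosphatase PhoX (TX72_RS09055) had 4941 ± 937 normalized reads in High-P and 5459 ± 761 in Low-P (0.15 ± 0.16, adjusted p = 0.468), and the phytase-like genes TX72_RS03725 and TX72_RS09060 had log2 fold changes of 0.79 ± 0.27 and 0.54 ± 0.26. Adjusted over the list alone, 5 and 1 uptake genes and 3 and 0 hydrolysis genes were higher and lower. Against all other genes the uptake list had a camera adjusted p of 0.164 and the hydrolysis list 0.224, and both had an adjusted p of 0.932 with an estimated correlation. Library High-P B had 0 reads for TX72_RS12645, TX72_RS14590, TX72_RS12775 and pstC. Without it their log2 fold changes were 4.40, 5.30, 4.25 and 2.56, each past the threshold. That fit made more false calls in simulated counts, which kept the spread estimated with High-P B. The call for TX72_RS12775 ended without Low-P A, B or C (6.54 to 6.99), that for TX72_RS05075 without Low-P A (1.20) or B (1.27), and that for pstB without High-P A (1.62), Low-P A (1.80) or Low-P B (1.78).

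**Figure D1:**
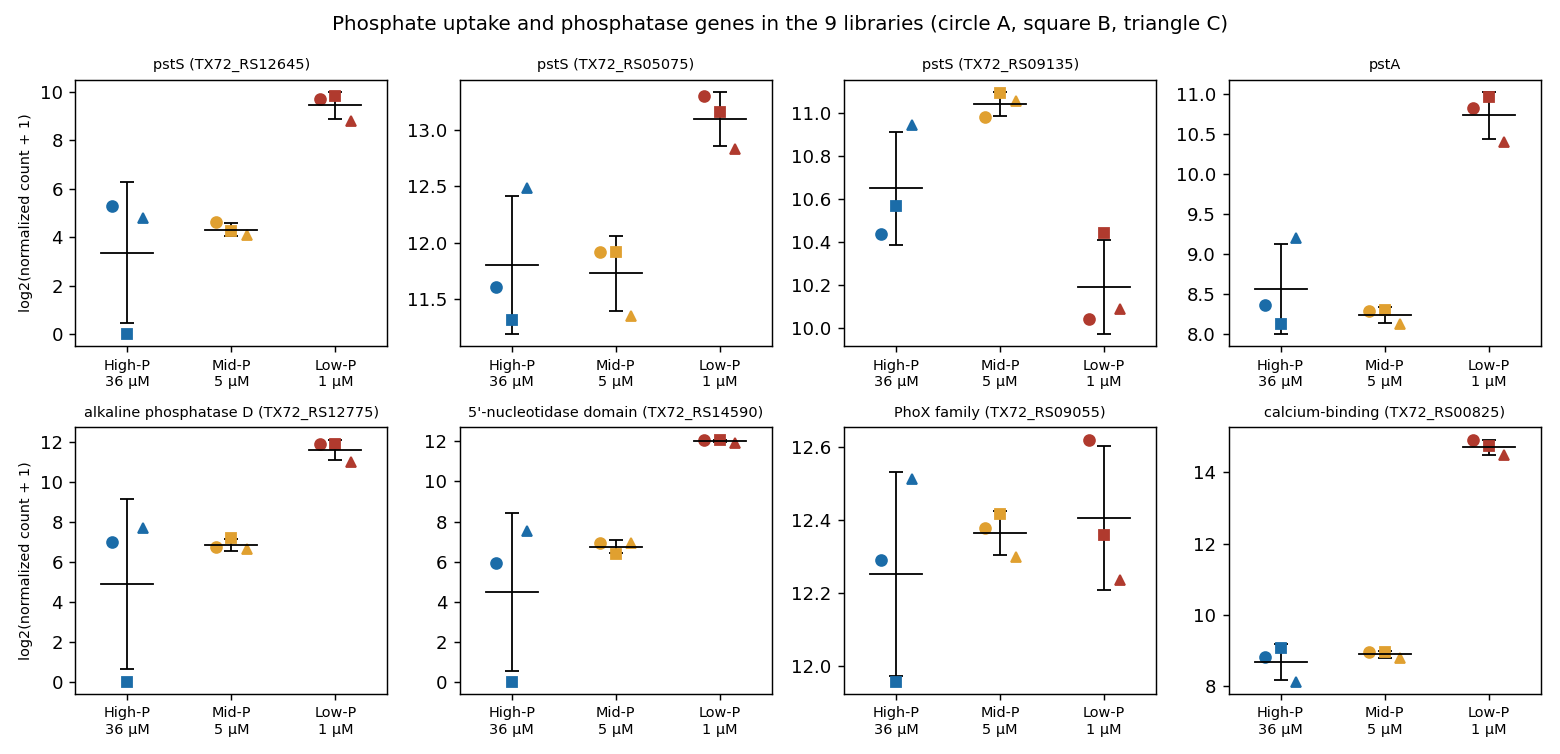
Normalized read counts, as log2(normalized count + 1), of phosphate uptake and organic phosphorus genes and of the calcium-binding gene TX72_RS00825 in High-P, Mid-P and Low-P. Each marker is 1 library (circle A, square B, triangle C), each line the group mean and each bar the SD over 3 libraries. The gene pstS (TX72_RS12645) averaged 21.6 and 19.1 normalized reads in High-P and Mid-P and 728 in Low-P, while the PhoX gene averaged 4941, 5277 and 5459.

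A calcium-binding protein gene (TX72_RS00825) rose from 423 ± 134 to 26952 ± 3953 normalized reads (log2 fold change 6.03 ± 0.24, adjusted p = 1.05e-05, limma) and had reads in every High-P library. Among the 10 genes with the largest positive change, the other 9 had a count of 0 in High-P B, so their fold depends on the added count of 1. They included crtD, a desaturase of carotenoid synthesis (5.51 ± 1.72, 3.11 without High-P B), a glycoside hydrolase family 3 gene (TX72_RS11130, 5.62 ± 1.77, 3.11 without High-P B) and genes of unknown function such as TX72_RS07610 (7.32 ± 1.35) and TX72_RS07895 (6.09 ± 0.79). The calls for crtD (adjusted p = 0.0467) and TX72_RS11130 (adjusted p = 0.0488) ended without each of Mid-P A, B and C and Low-P A, B and C, at log2 fold changes of 5.35 to 5.77 and 5.57 to 5.68. The call for TX72_RS11130 also ended with library medians set equal (5.48, adjusted p = 0.0505).

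Among the 10 largest falls were coxB, of cytochrome c oxidase, and genes of heme synthesis. The oxidase subunit gene coxB fell from 56974 ± 16873 to 4557 ± 1513 normalized reads (log2 fold change -3.65 ± 0.27, adjusted p = 0.000146). Neighbouring locus tags for heme A synthase (TX72_RS09365), heme o synthase (TX72_RS09360) and an ABC transporter protein (TX72_RS09355) had log2 fold changes of -4.12 ± 0.40, -4.10 ± 0.35 and -3.63 ± 0.32. An iron uptake porin gene (TX72_RS11220) fell 21.1-fold, from 227812 ± 152973 to 9527 ± 1973 normalized reads (-4.40 ± 0.41). A Nif11 family peptide gene (TX72_RS13090) had the most negative change of those named by rule (-5.22 ± 0.58), and bsmB, a methyltransferase of glycine betaine synthesis, fell 12.0-fold (-3.58 ± 0.40). All of these calls held in each of the 9 fits that left out 1 library.

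Of 21 phycobilisome genes, which encode the antenna proteins and their linkers, 12 rose and none fell in Low-P (13 and 0 adjusted over the list alone), and 9 were not called, with a median log2 fold change of 0.81, or 0.46 above the median of all genes. The linker genes TX72_RS02350 and TX72_RS10065 rose by 1.33 ± 0.14 and 1.54 ± 0.17. The list passed the camera test (adjusted p = 0.00713, and adjusted p = 0.932 with an estimated correlation), and its call ended without High-P A (adjusted p = 0.0765), without High-P B (0.0706) or, in the Low-P versus High-P fit, with library medians set equal (0.0587; range over the fits without 1 library 0.00307 to 0.0765). Of 35 photosystem II genes 9 rose and 5 fell, among the former psbQ (1.89 ± 0.26) and the photosystem II protein Y gene TX72_RS04455 (1.75 ± 0.15). These counts became 11 and 1 with library totals set equal and 9 and 7 with library medians set equal. Of 14 photosystem I genes 1 rose and 2 fell (1 and 0 with equal totals, 0 and 4 with equal medians), with a median of -0.23 that became 0.06 with library totals set equal. Among 14 carbon fixation genes 3 rose and 3 fell. A phosphoribulokinase gene (TX72_RS03850) rose by 1.78 ± 0.15, and genes with CP12 domains, found in a small inhibitor of the Calvin cycle, had log2 fold changes of -2.35 ± 0.21 (TX72_RS07310) and -1.42 ± 0.17 (TX72_RS09680). Of 9 ATP synthase genes only atpB passed (2.06 ± 0.28). The list did not pass the camera test (adjusted p = 0.265) but did without High-P C (0.00758).

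**Figure D2:**
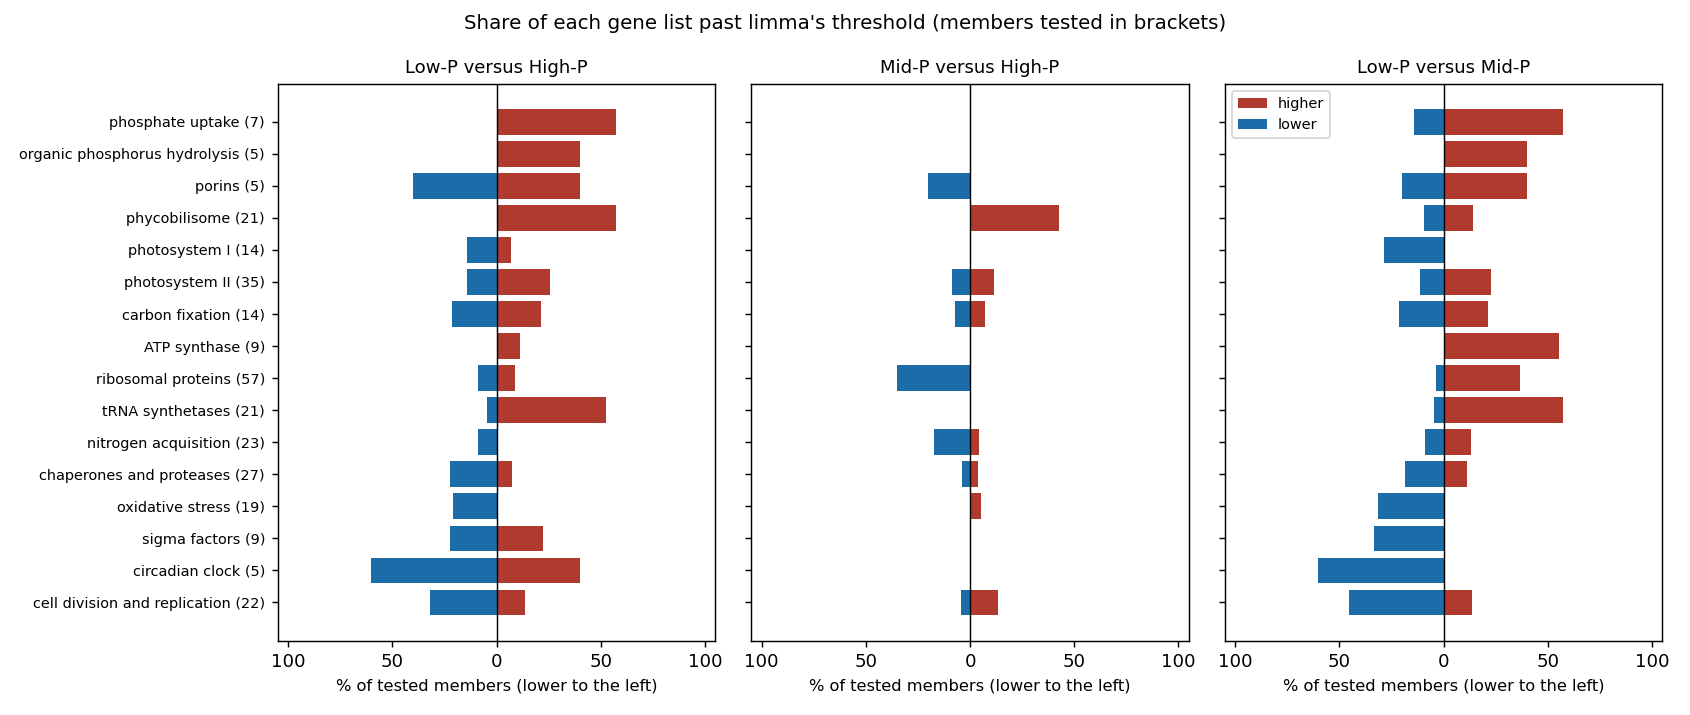
For each gene list, the percent of tested members called higher (to the right of 0) or lower (to the left) at an adjusted p under 0.05 in the 3 comparisons. In Low-P versus High-P 12 of 21 phycobilisome genes and 11 of 21 tRNA synthetase genes were higher, and in Mid-P versus High-P 20 of 57 ribosomal protein genes were lower.

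Of 21 tRNA synthetase genes, which load amino acids onto tRNAs, 11 rose and 1 fell (11 and 1 adjusted over the list alone), with a median log2 fold change of 1.05, or 0.69 above that of all genes. The camera adjusted p was 0.00538 (adjusted p = 0.314 with an estimated correlation) and passed in all 9 fits without 1 library. Examples were aspS (1.38 ± 0.21) and ileS (1.15 ± 0.18), against serS (-1.66 ± 0.24). Of 57 ribosomal protein genes 5 rose and 5 fell, a split that became 5 and 14 with library medians set equal, 8 and 2 with library totals set equal and 6 and 12 by edgeR. The gene rplC rose from 8281 ± 1509 to 37914 ± 7235 normalized reads (2.19 ± 0.19) and rplD by 2.00 ± 0.24, while rpsT fell by 1.04 ± 0.14 on the log2 scale.

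Among 23 nitrogen acquisition genes none rose and 2 fell. They were an ammonium transporter gene (TX72_RS01260), from 86778 ± 11190 to 11899 ± 4451 normalized reads (-2.92 ± 0.26, adjusted p = 0.000165), and the gene of a P-II nitrogen regulator (TX72_RS02220, -0.87 ± 0.16, with an adjusted p of 0.0624 when library totals were set equal). All 5 clock genes passed, as kaiA (TX72_RS02655, -2.43 ± 0.26), kaiC (-1.15 ± 0.21) and kaiB fell and both rpaB genes rose (TX72_RS00635 by 1.06 ± 0.21). Of 9 sigma factor genes 2 rose and 2 fell, with TX72_RS07580 at -2.10 ± 0.24. These counts became 0 and 3 with library medians set equal and 3 and 2 with library totals set equal. Of 19 oxidative stress genes 4 fell and none rose, including sodN, the nickel superoxide dismutase (-1.25 ± 0.16), and a thioredoxin family gene (TX72_RS07650, -2.14 ± 0.29). Of 22 cell division and replication genes 3 rose and 7 fell (gyrA -1.42 ± 0.13, minD -1.05 ± 0.12), and of 27 chaperone and protease genes 2 rose and 6 fell (clpX -1.74 ± 0.23). With library totals set equal these counts of higher and lower genes became 4 and 3 for cell division and 4 and 3 for chaperones, and with library medians set equal 1 and 9 and 1 and 7. Median log2 fold changes of the nitrogen, oxidative stress, cell division and chaperone lists (-0.29 to -0.12) became 0.00 to 0.17 with library totals set equal, as did that of the ribosomal list (-0.02 to 0.27). Every tested list apart from the phycobilisome and tRNA synthetase lists had a camera adjusted p of 0.164 or more.

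Smaller lists held few calls. Of 4 polyphosphate genes an inorganic diphosphatase rose (TX72_RS09010, 1.27 ± 0.24), of 8 phospholipid genes 2 rose and 1 fell, and of 7 arsenic and chromate genes chrA fell (-1.51 ± 0.16) and an arsenate reductase gene rose (TX72_RS08905, 1.10 ± 0.26, not past the threshold without Low-P A, 1.00, or Low-P B, 1.05). Of 5 porin genes 2 rose and 2 fell. None of 8 high-light inducible genes rose and 1 fell, and their median of 2.43 rested on zeros in High-P B and was 0.08 without that library. Of 4 stable RNA genes 0 passed by limma (3 at an unadjusted p under 0.05) and 1 was lower by edgeR. The metallothionein gene of the zinc list fell (TX72_RS12955, -0.95 ± 0.23, not past the threshold without Low-P A, -0.84, or Low-P C, -0.87, or with library totals set equal, -0.66), and the SwmB domain gene of the swimming list rose (TX72_RS13810, 1.18 ± 0.23). The single genes for iron (TX72_RS09050, 0.43 ± 0.26) and phosphonate transport (TX72_RS05870, 2.35 ± 1.79, -0.15 without High-P B) did not pass, and the sulfolipid and glycolipid list had 0 members. The list named phosphate regulation took in 34 genes by its text pattern, mostly for nucleotide synthesis and sugar phosphorylases and none for a phosphate regulator. Of these 4 rose and 5 fell, such as glmU (2.03 ± 0.21) and a glycogen phosphorylase gene (TX72_RS00785, -1.64 ± 0.16). With library totals set equal the counts of this list became 7 and 4, and with library medians set equal those of the phospholipid list 1 and 3. For the phospholipid, arsenic, porin, sigma factor and high-light inducible lists the camera direction was down although the median was above 0, and medians and means had opposite signs for the porin, ribosomal, nitrogen, chaperone, oxidative stress and stable RNA lists. With library medians set equal the polyphosphate median of 0.12 turned to -0.09.

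In all, 705 of 2684 tested genes changed between Low-P and High-P (26.3%), 337 higher and 368 lower, and 490 of them by at least 2-fold. The split became 243 higher and 504 lower with library medians set equal and 553 and 225 with library totals set equal. The median log2 fold change of all genes was 0.36 here, 0.30 in Mid-P versus High-P and 0.14 in Low-P versus Mid-P, and it became 0.15, 0.22 and 0.01 with equal medians and 0.65, 0.01 and 0.72 with equal totals. Libraries of the groups did not overlap for 1325 genes (49.4%), where chance gives 10%. Without High-P B 1269 genes passed, without Low-P A 378 and without Low-P B 398. In simulated counts with the real depths, 49 of 2479 unchanged genes were called in this comparison (34.3% of the simulated calls). Without High-P B it was 212 of 2477 (63.9% of the simulated calls). A part of the calls of the main fit is therefore open to doubt. The simulation without High-P B kept the spread estimated with that library. It therefore leaves open how many calls of that real fit are false. A fit of these groups alone called 388 genes in the real data, and 7 of 2475 unchanged genes in simulated counts.

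The Mid-P and High-P cultures were compared to separate the effect of a moderate from a plentiful phosphate supply. Of the 7 phosphate uptake and 5 organic phosphorus genes 0 passed by limma and 0 by edgeR (1 of each list at an unadjusted limma p under 0.05). The gene pstS (TX72_RS12645) had 19.1 ± 3.83 normalized reads in Mid-P and 21.6 ± 19.7 in High-P (log2 fold change 0.95 ± 1.29), pstA 302 ± 21.3 and 398 ± 165 (-0.32 ± 0.29), and the PhoX gene TX72_RS09055 5277 ± 219 and 4941 ± 937 (0.11 ± 0.16, n = 3 each). The log2 change of this pstS gene is above 0 although its Mid-P mean was lower, because of its 0 in High-P B. The medians of the uptake and hydrolysis lists (0.27 and 0.11) turned to -0.02 and -0.18 with library totals set equal and to -0.11 and -0.38 without High-P B.

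Of 57 ribosomal protein genes 20 fell in Mid-P and none rose (32 and 1 adjusted over the list alone), with a median log2 fold change of -0.77, or -1.07 relative to all genes (camera adjusted p = 5.42e-15; adjusted p = 0.598 with an estimated correlation). The genes rplJ and rplL fell from 6008 ± 1280 to 1669 ± 31.9 and from 3734 ± 1309 to 906 ± 54.2 normalized reads (-1.83 ± 0.16 and -1.99 ± 0.23), and rpsG by 1.52 ± 0.20 on the log2 scale. Of 9 ATP synthase genes 0 passed by limma (1 at an unadjusted p under 0.05) and 1 was lower by edgeR, and the list had a median of -0.91 (camera adjusted p = 0.0224; adjusted p = 0.694 with an estimated correlation). Their messages were highest in High-P C, with 3034 normalized reads of the subunit B' gene (TX72_RS02375) there against 461 and 967 in High-P A and B, and in Mid-P versus High-P the list's call ended without High-P C (adjusted p = 0.407) or High-P B (0.0938; range over the fits without 1 library 2.22e-05 to 0.407).

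Of 21 phycobilisome genes 9 rose, none fell and 12 were not called (13 and 0 higher and lower adjusted over the list alone). With library medians set equal 7 rose, and with library totals set equal 4. The list had a median of 0.58, or 0.28 above all genes (camera adjusted p = 0.000315; adjusted p = 0.694 with an estimated correlation). The linker genes TX72_RS10015 and TX72_RS10075 rose by 1.66 ± 0.20 and 1.76 ± 0.30, the call for TX72_RS10075 ending without Mid-P A (1.63). Of 35 photosystem II genes 4 rose and 3 fell. Those that fell were psbA genes, which encode the D1 protein of the reaction center, such as TX72_RS09645, from 25877 ± 6378 to 6702 ± 1445 normalized reads (-1.94 ± 0.25, adjusted p = 0.00423), and TX72_RS04900 (-1.41 ± 0.21). The psbA copies are close relatives, and reads that fit more than 1 of them may have been divided or dropped, so each value is uncertain. Of 14 photosystem I genes 0 passed by limma (5 at an unadjusted p under 0.05) and 2 were higher by edgeR, with psaC at 1.28 ± 0.35 (adjusted p = 0.0518). Among 14 carbon fixation genes 1 rose and 1 fell, both with CP12 domains, TX72_RS06960 (2.15 ± 0.50) and TX72_RS07310 (-0.99 ± 0.21). The call for TX72_RS06960 ended without High-P A, any 1 of Mid-P A, B and C or any 1 of Low-P A, B and C (1.96 to 2.26) and that for TX72_RS07310 without Mid-P A, B or C (-1.05 to -0.87).

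Of 23 nitrogen acquisition genes 1 rose, 4 fell and 18 were not called (1 and 7 higher and lower adjusted over the list alone). The P-II regulator gene (TX72_RS02220) rose 3.23-fold, from 2597 ± 521 to 8273 ± 201 normalized reads (1.69 ± 0.16, adjusted p = 0.00146), while urtC (-1.93 ± 0.37) and the substrate-binding gene TX72_RS12370 (-2.73 ± 0.53) of the urea transporter fell. The list's camera adjusted p of 0.0237 (adjusted p = 0.694 with an estimated correlation) became, for Mid-P versus High-P, 0.289 without High-P C and 0.133 with library totals set equal (range over the fits without 1 library 0.00125 to 0.289), and TX72_RS12370 had 5705 normalized reads in High-P C against 1774 and 2387 in High-P A and B. The call for urtC ended without Mid-P A (-1.86) or B (-1.91), and that for TX72_RS12370 without Mid-P A, B or C (-2.84 to -2.67). Of 5 porin genes 1 fell (TX72_RS10695, -1.14 ± 0.18) and the list passed the camera test (adjusted p = 0.0224; adjusted p = 0.694 with an estimated correlation), a call lost without High-P C (0.248; range over the fits 0.00592 to 0.248).

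Among the 27 chaperone and protease genes 1 rose and 1 fell (1 and 0 adjusted over the list alone). The chaperonin gene groL (TX72_RS02485) fell from 14452 ± 17062 to 508 ± 42.4 normalized reads (-3.86 ± 0.98, adjusted p = 0.0411), and outside the list a small heat shock protein gene (Hsp20 family, TX72_RS11950) fell from 22679 ± 27348 to 349 ± 129 (-5.08 ± 0.95, adjusted p = 0.0145). Both were far higher in High-P C than in the other High-P libraries, with 2251, 12038 and 53747 normalized reads of TX72_RS11950 and 1476, 8101 and 33779 of TX72_RS02485 in High-P A, B and C. The call for TX72_RS02485 ended without each of Mid-P A, B and C and Low-P A, B and C (-3.93 to -3.83) and that for TX72_RS11950 without Mid-P A (-4.91) or B (-4.96). TX72_RS13910, of unknown function, fell by 3.31 ± 0.60 on the log2 scale, and a Clp protease subunit gene rose (TX72_RS06540, 1.13 ± 0.16).

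The largest rises in Mid-P that held without each library were in the DUF4278 domain genes TX72_RS13220, from 1369 ± 607 to 33176 ± 18627 normalized reads (4.48 ± 0.58, adjusted p = 0.00399), and TX72_RS13165, from 8868 ± 5074 to 130557 ± 44432 (4.02 ± 0.55), and in TX72_RS04575, a gene of unknown function (3.20 ± 0.24). TX72_RS14840 (4.70 ± 0.96) and TX72_RS07895 (4.16 ± 0.79) lost their calls without Mid-P A, B or C, at 4.50 to 4.80 and 4.02 to 4.38. Of the remaining lists, tRNA synthetases had 0 of 21 past the threshold by limma and 1 lower by edgeR, sigma factors 0 of 9 by limma and 1 higher by edgeR, and the 5 clock, 8 high-light inducible and 4 stable RNA genes had 0 by limma and 0 by edgeR. At an unadjusted limma p under 0.05 these 5 lists held 1, 4, 2, 1 and 1 genes. Oxidative stress had 1 of 19 higher, cell division 3 higher and 1 lower of 22, polyphosphate 1 of 4 higher, phospholipid 1 of 8 lower, arsenic 1 of 7 lower (chrA, -1.05 ± 0.16), and the nucleotide and phosphorylase genes of the phosphate regulation list 1 higher and 2 lower of 34. The single iron, zinc and phosphonate genes (-0.11 ± 0.26, 0.43 ± 0.23 and 2.51 ± 1.79) and both swimming genes did not pass by limma, and edgeR called 1 swimming gene lower. Camera adjusted p of these lists were 0.0969 or more, but the sigma factor list passed without High-P B (0.00535) and the clock and chaperone lists without High-P A (0.0474 and 0.0396). With library totals set equal the counts of higher and lower genes became 1 and 2 for cell division, 3 and 5 for photosystem II and 0 and 1 for oxidative stress. Their directions are uncertain in part, since with library totals set equal medians above 0 fell below it for the polyphosphate, both photosystem, chaperone, oxidative stress, tRNA synthetase, cell division and stable RNA lists (-0.23 to -0.01). For the uptake, hydrolysis, carbon fixation, chaperone, high-light inducible and tRNA synthetase lists the camera direction was down with a median above 0, and medians and means had opposite signs for the chaperone, phosphate regulation, arsenic and phospholipid lists.

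Between Mid-P and High-P 302 genes changed (11.3%), 182 higher and 120 lower, 200 of them by at least 2-fold, and the split became 160 and 130 with equal medians and 96 and 248 with equal totals. Libraries did not overlap for 968 genes (36.1%; chance 10%). Without Mid-P A, B or C 85, 112 or 139 genes passed, without Low-P A or B 194 each, and without High-P A or B 468 or 628. In simulated counts 49 of 2479 unchanged genes were called (38.3% of the simulated calls). Without High-P B it was 260 of 2480 (70.5% of the simulated calls), with the spread still estimated with that library. A fit of these groups alone called 90 genes in the real data, and 5 of 2475 unchanged genes in simulated counts.

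**Figure D3:**
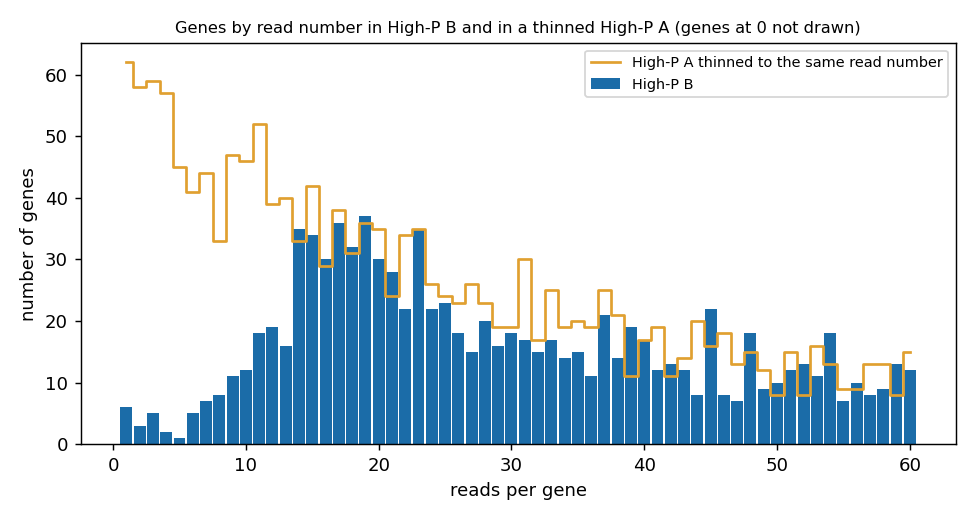
Number of genes (vertical axis) by their number of reads (horizontal axis) in High-P B and in High-P A thinned at random to the same total. High-P B held 22 genes with 1 to 6 reads, against 322 in the thinned High-P A, and 234 against 244 with 14 to 20 reads.

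The Low-P and Mid-P cultures were compared to show what differs between the lowest and the moderate phosphate supply. Of 7 uptake genes 4 rose and 1 fell (5 and 1 adjusted over the list alone). The gene pstA rose 5.64-fold, from 302 ± 21.3 to 1729 ± 335 normalized reads (adjusted p = 0.000420, limma, n = 3 each), pstS (TX72_RS12645) 35.0-fold (5.13 ± 1.29), pstS (TX72_RS05075) 2.59-fold (1.37 ± 0.31) and pstB 3.21-fold (1.68 ± 0.50), while pstS (TX72_RS09135) fell by 0.85 ± 0.17 on the log2 scale, not past the threshold with library totals set equal (-0.27). The gene pstC had 274 ± 9.90 and 1769 ± 296 normalized reads (2.67 ± 1.92, adjusted p = 0.382), with a standard error that comes from its 0 in High-P B. Of 5 hydrolysis genes 2 rose (4 and 0 adjusted over the list alone), TX72_RS14590 (5.28 ± 1.61) and the phytase-like gene TX72_RS03725 (1.49 ± 0.27). TX72_RS12775 had 114 ± 24.2 and 3190 ± 1002 normalized reads (4.75 ± 1.74, adjusted p = 0.0759) and the PhoX gene a log2 fold change of 0.04 ± 0.16. The standard error of TX72_RS12775 also takes in its 0 in High-P B, a library outside this comparison. In the fit without High-P B 6 uptake genes were higher and 1 lower, and 4 hydrolysis genes were higher and 0 lower. Both lists had a camera adjusted p of 0.0852 and an adjusted p of 0.642 with an estimated correlation, and both passed without High-P B (0.0372). The calls for TX72_RS12645 (4.94 to 5.28) and pstB (1.51 to 1.76) ended without Mid-P A, B or C or Low-P A or B, and that for TX72_RS14590 without these or Low-P C (5.09 to 5.38).

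Of 9 ATP synthase genes 5 rose from Mid-P to Low-P (8 adjusted over the list alone), among them atpB from 1411 ± 42.0 to 6401 ± 806 normalized reads (2.17 ± 0.28), with a list median of 2.11, or 1.97 above all genes (camera adjusted p = 0.00242; adjusted p = 0.642 with an estimated correlation). Of 57 ribosomal protein genes 21 rose and 2 fell (23 and 4 adjusted over the list alone), with a median of 0.63, or 0.49 above all genes (camera adjusted p = 4.14e-05; adjusted p = 0.642 with an estimated correlation). The genes rplC and rplD rose by 3.54 ± 0.19 and 3.39 ± 0.24 on the log2 scale, and rplJ had 1669 ± 31.9 normalized reads in Mid-P and 6242 ± 750 in Low-P (1.90 ± 0.16). Of 21 tRNA synthetase genes 12 rose and 1 fell (15 and 1 adjusted over the list alone), such as ileS (1.38 ± 0.18) and hisS (1.74 ± 0.29) against serS (-2.17 ± 0.24). Their median was 1.15, or 1.01 above all genes (camera adjusted p = 0.000232; adjusted p = 0.164 with an estimated correlation). These 3 list calls held in all 9 fits without 1 library.

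The strongest falls from Mid-P to Low-P were in the Nif11 gene TX72_RS13090, from 10665 ± 2795 to 61.1 ± 20.4 normalized reads (-7.45 ± 0.58, adjusted p = 8.45e-05), in TX72_RS02625 (-6.43 ± 0.57) and TX72_RS05785 (-5.58 ± 0.38), of unknown function, and in the DUF4278 genes TX72_RS13220 and TX72_RS13165 (-5.91 ± 0.58 and -5.73 ± 0.55). The calcium-binding protein gene TX72_RS00825 rose 56.3-fold (5.82 ± 0.24), and the heat shock gene TX72_RS11950 from 349 ± 129 to 12011 ± 454 normalized reads (5.16 ± 0.95). TX72_RS07610 rose by 5.24 ± 1.35, a call that ended without each of Mid-P A, B and C and Low-P A, B and C (4.96 to 5.39). The ammonium transporter gene TX72_RS01260 and the P-II gene TX72_RS02220 fell (-2.80 ± 0.26 and -2.56 ± 0.16) and the urea transporter gene TX72_RS12370 rose (2.21 ± 0.53, not past the threshold without Mid-P B, 2.15), in all 3 of 23 nitrogen genes higher and 2 lower.

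**Figure D4:**
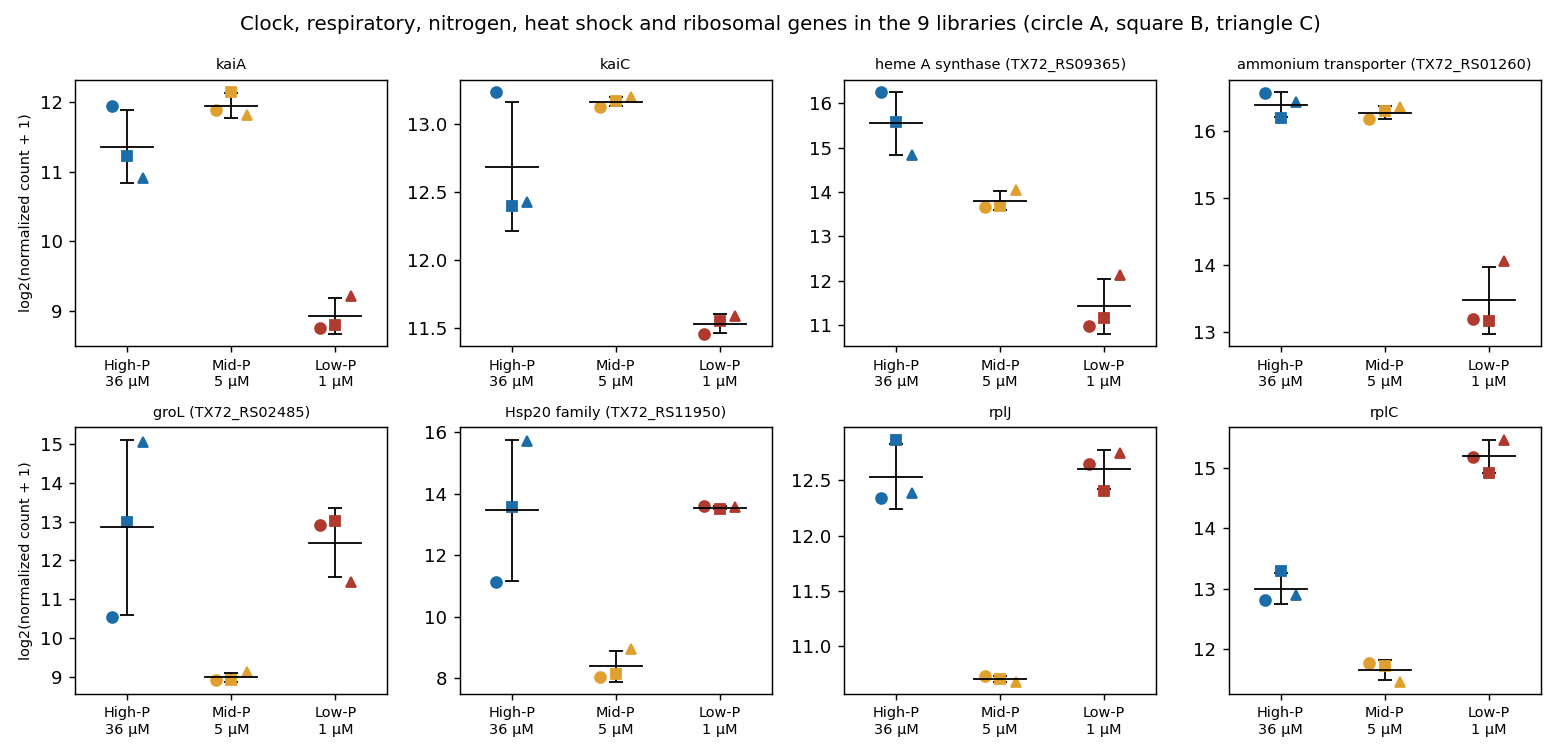
Normalized read counts, as log2(normalized count + 1), of genes outside phosphate metabolism in High-P, Mid-P and Low-P; each marker is 1 library (circle A, square B, triangle C), each line the group mean and each bar the SD over 3 libraries. The panels show kaiA, kaiC, the genes of heme A synthase and of an ammonium transporter, groL, a small heat shock protein gene, rplJ and rplC.

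The clock genes kaiA (-3.02 ± 0.26), kaiC (-1.63 ± 0.21) and kaiB (-1.36 ± 0.30) fell from Mid-P to Low-P, the call for kaiB ending with library totals set equal (-0.78). Of 9 sigma factor genes 3 fell, led by TX72_RS12290 (-4.05 ± 0.63) and TX72_RS07580 (-2.85 ± 0.24), and of 19 oxidative stress genes 6 fell, among them TX72_RS07650 (-3.20 ± 0.29) and sodN (-1.58 ± 0.16). Of 22 cell division and replication genes 10 fell and 3 rose (gyrA -1.57 ± 0.13), and of 27 chaperone and protease genes 5 fell (clpX -2.38 ± 0.23) and 3 rose. Of 14 photosystem I genes 4 fell, with a median of -0.47 that became 0.11 with equal totals, and of 35 photosystem II genes 8 rose and 4 fell (TX72_RS04455 1.32 ± 0.15, psbH -1.35 ± 0.24). With library totals set equal the counts of higher and lower genes turned to 7 and 3 for cell division, 9 and 3 for chaperones and 4 and 0 for photosystem I. They became 3 and 3 for oxidative stress, 15 and 1 for photosystem II, 11 and 0 for the phycobilisome, 6 and 2 for carbon fixation, 10 and 2 for nitrogen and 12 and 2 for phosphate regulation. Of 21 phycobilisome genes 3 rose and 2 fell, and the linker gene TX72_RS02335 had -0.50 ± 0.13, which turned to 0.09 with equal totals and was not past the threshold without Mid-P C (-0.39), Low-P B (-0.50) or Low-P C (-0.44). Carbon fixation had 3 genes higher and 3 lower of 14 (TX72_RS03850 1.96 ± 0.15, CP12 gene TX72_RS07310 -1.36 ± 0.21), and porins 2 higher (TX72_RS11210 3.08 ± 0.52) and 1 lower of 5 (TX72_RS11220 -3.13 ± 0.41).

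In the smaller lists 1 of 4 polyphosphate genes rose and 1 fell, 2 of 8 phospholipid genes rose and 2 fell, the phosphate regulation list had 6 higher and 7 lower of 34, and the RNase P RNA gene rnpB fell (-2.85 ± 0.54) as the only 1 of 4 stable RNA genes to pass. The metallothionein gene TX72_RS12955 fell (-1.38 ± 0.23) and the SwmB domain gene TX72_RS13810 rose (1.65 ± 0.23). Of 7 arsenic genes 0 passed by limma, with 1 higher and 1 lower by edgeR, and of 8 high-light inducible genes 0 passed by limma and 0 by edgeR (1 of each list at an unadjusted limma p under 0.05). The iron gene TX72_RS09050 (0.54 ± 0.26) and the phosphonate gene TX72_RS05870 (-0.16 ± 1.79) did not pass. Medians of the sigma factor, oxidative stress, cell division, polyphosphate, high-light inducible and phycobilisome lists (-0.18 to -0.01) became 0.40 to 0.57 with library totals set equal, so no direction is given for them. The lists without a camera call had adjusted p of 0.0852 or more. The camera direction was up for phycobilisome and polyphosphate genes with a median below 0 and down for chaperones and stable RNA with a median above 0, and medians and means had opposite signs for the high-light inducible, polyphosphate and stable RNA lists.

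Between Low-P and Mid-P 776 genes changed (28.9%), 327 higher and 449 lower, 549 of them by at least 2-fold. The split became 268 and 527 with equal medians and 763 and 222 with equal totals. Libraries did not overlap for 1905 genes (71.0%; chance 10%). In simulated counts 0 of 2478 unchanged genes were called, and 13 of 100 changed 2-fold and 65 of 100 changed 4-fold were found. A fit of these groups alone found 96 of 100 and 100 of 100, with 4 of 2482 unchanged genes called, and in the real data it called 1793 genes. The fit without High-P B, which leaves these groups whole, called 1471 genes.

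Across the 3 levels 939 of 2684 genes differed by the limma F test (1727 without High-P B, 579 without Low-P A and 620 without Low-P B). Ordered by group mean, 285 of them (30.4%) ran Mid-P over High-P over Low-P, 176 Low-P over High-P over Mid-P, 170 Low-P over Mid-P over High-P and 159 High-P over Mid-P over Low-P. The step from High-P to Mid-P held 302 calls and the step from Mid-P to Low-P 776, a ratio of 2.57, which rose to 6.45, 4.95 and 4.36 without Mid-P A, B and C. Phosphate uptake genes had medians of 0.27 for the step to Mid-P and 1.68 for the step to Low-P, ribosomal protein genes -0.77 and 0.63, ATP synthase genes -0.91 and 2.11, and phycobilisome genes 0.58 and -0.08, the last turning to 0.50 and the earliest to -0.02 with library totals set equal. Whether the steps differ in size was not tested.

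Low-P versus High-P and Mid-P versus High-P shared 100 calls in the same direction (58 higher, 42 lower) and 49 in opposite directions. Independent lists of these sizes would share 39.3 (22.9 and 16.5). For simulated unchanged groups all 9 libraries were drawn anew around the High-P means, and both comparisons used the same simulated High-P libraries. They shared 19.4 calls on average and 43 at most, with 0 in opposite directions. The covariance of the log2 fold changes was 1.40, within the range of the simulated values (mean 1.23, highest 1.42). Their correlation was 0.67, against a simulated mean of 0.98, and 67.1% of genes had the same sign, against 84.9%. The 3 High-P libraries are too few to be split between the comparisons, so part of the overlap may come from the shared High-P libraries. Without High-P A, B or C the overlap was 160, 244 or 199, without Mid-P A, B or C 27, 45 or 40, and without Low-P A, B or C 50, 48 or 64.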

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

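Of the tests in this section, those on few molecules read many times and on the time of day had predictions written before the test was run, and all others were chosen after the result was seen.

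A signal appeared in sequences that the comparisons did not use. The normalized table listed 6 ERCC spike-in sequences although the labels mention no spike-in, and reads were assigned to them above the limit that a count of 0 allows in High-P C (37 reads), Mid-P A (10), Mid-P B (6), Low-P A (8), Low-P B (24) and Low-P C (22). Mid-P C had 3, and High-P A and B had 0. These reads made up at most 0.000704% of a library, and their source was not tested.

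The mean log2 change of 9 heat shock genes, chosen after the data were seen, from High-P to Mid-P was -3.03 ± 1.33 (SE over libraries, n = 3 each). The 27 chaperone and protease genes chosen beforehand had a median of 0.06 and a mean of -0.54 there, with 1 higher and 1 lower. Of the 9 genes 2 passed the test as lower in Mid-P, and all 9 were highest in High-P C. Their geometric means were 687, 2413 and 16292 normalized reads in High-P A, B and C and 343, 358 and 407 in the Mid-P libraries. In Low-P A, B and C they were 3577, 3784 and 1683, above every Mid-P library. Without High-P C the change was -1.81 ± 0.68, and 3 of the 9 genes passed the test, so whether 1 High-P library sets the difference remains open. Scaling can be excluded, since the change was -3.10 or lower under the other scalings. A fall that continues as phosphate falls can be excluded too. The mean change from Mid-P to Low-P was 2.94 ± 0.38, with 3 of the 9 genes called higher and none lower. That change does not exclude a rise at low phosphate, because the difference between High-P and Mid-P remains open. A stress in some cultures that is unrelated to phosphate may explain the pattern but was not tested. If such a stress also set the rise from Mid-P to Low-P, it would have to include every Low-P culture. Whether phosphate set that rise was not tested.

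High-P B had 671 genes at 0. A lower read number alone can be excluded, since High-P A and C thinned to its depth had at most 100 genes at 0 in 20 draws each. Of the 671 genes 110 had 20 or more expected reads, which goes against a filter that set low values to 0. It does not exclude a filter, since expected reads came from High-P A and C. Their Spearman correlations with High-P B were only 0.870 and 0.859. Few molecules read many times may explain it, since only 14 genes had 1 to 3 reads, against 152 to 177 in the thinned libraries, as predicted for that cause.

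The clock genes kaiA, kaiB and kaiC, the oxidase gene coxB and the sigma factor gene TX72_RS07580 were lower in Low-P than in both other groups, while both rpaB genes of the clock list and 2 of 9 sigma factor genes were higher in Low-P than in High-P. With library medians set equal 0 of the 9 sigma factor genes were higher there. If the cultures had been harvested at different times of day, genes of sugar oxidation that peak at dusk should also be lower in Low-P, and their median change from Mid-P to Low-P was -1.99 relative to all genes. All 4 fell, with opcA at -1.91 ± 0.13, zwf at -1.78 ± 0.31, gndA at -0.89 ± 0.21 and transaldolase at -2.42 ± 0.20. A difference in the time of day at harvest may therefore explain the falls. An effect of phosphate on the same genes remains open, because time and treatment would coincide.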

How the results depend on the processing

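Depth and spread in High-P limit most results. Without High-P B the calls rose to 1269 in Low-P versus High-P, 628 in Mid-P versus High-P, 1471 in Low-P versus Mid-P and 1727 across the levels. In simulated counts, however, that fit called 212 of 2477 and 260 of 2480 unchanged genes in the comparisons with High-P. These were 63.9% and 70.5% of its simulated calls, shares that depend on the number of changed genes put in. The simulated counts kept the spread estimated with High-P B, so they do not measure the false calls of the real fit. The lowest counts without 1 library were 378 (without Low-P A), 85 (without Mid-P A), 537 (without Low-P A) and 579 (without Low-P A). Shared calls of the comparisons with High-P ranged from 27 (without Mid-P A) to 244 (without High-P B), and the ratio of the steps from 1.90 (without High-P A) to 6.45 (without Mid-P A). Lists past the camera threshold ranged from 1 (without High-P A or B) to 3 (without High-P C) in Low-P versus High-P, from 2 (without High-P C) to 7 (without High-P A) in Mid-P versus High-P and from 3 to 5 (without High-P B) in Low-P versus Mid-P.

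Fits of only the 2 groups compared called 388, 90 and 1793 genes in Low-P versus High-P, Mid-P versus High-P and Low-P versus Mid-P, since each fit then carries the spread of its own groups, and 5 lists in the last. In simulated counts these fits called 7 and 5 of 2475 unchanged genes in the comparisons with High-P, against 49 of 2479 in each for the main fit. They also found fewer genes changed 4-fold there, 53 and 36 of 100 against 77 and 59. DESeq2 called 1058 and 595 in the comparisons with High-P and 1470 across the levels. A fit with array weights called 1821 in Low-P versus Mid-P and 1855 across the levels, with 4 lists in Low-P versus High-P and 5 in Low-P versus Mid-P. A limit of at least 2-fold left 200 calls in Mid-P versus High-P by construction. With an estimated correlation 0, 0 and 0 lists passed in the 3 comparisons, and by fry 5, 3 and 13. Equal library medians left 1 list in Low-P versus High-P. Among 286 values of named genes, 1 that was called in either fit reversed, TX72_RS02335 from -0.50 to 0.0856 in Low-P versus Mid-P under equal library totals. That setting also ended 26 other calls, added 21 and changed the sign of 10 values called in neither fit. Fits of only the 2 groups ended 37 calls, the replicate block 24 and the fit without Low-P A 40, the most of any setting. For DESeq2, array weights, fry and the scalings the cause was not tested. A filter of at least 20 expected reads in High-P B, chosen after its depth was seen, left 663, 354, 794 and 938 calls.

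With a replicate block, 523, 153 and 657 genes were called in Low-P versus High-P, Mid-P versus High-P and Low-P versus Mid-P, all but 5, 0 and 1 of them also called without it, and the shared calls fell to 47. Libraries with the same letter had residual correlations of -0.22 to 0.12 over 9 pairs, and not every library correlated best with its own letter. Pairing by letter was therefore not seen, but 3 libraries per group are too few to exclude it.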

Other observations

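Lists in this section were chosen after the data were seen. Of 18 genes of the NDH-1 complex, which passes electrons from NADPH or ferredoxin to plastoquinone, 2 rose and 9 fell against High-P (median log2 fold change -0.90, camera adjusted p = 0.00122; adjusted p = 0.267 with an estimated correlation), and 3 rose and 9 fell against Mid-P (-0.68, camera adjusted p = 0.0176; adjusted p = 0.387). The genes of subunit L (TX72_RS07640) and of a subunit 4 (TX72_RS11415) fell by 1.95 ± 0.28 and 1.76 ± 0.27 against High-P on the log2 scale, while those of another subunit 4 (TX72_RS07445) and of subunit F (TX72_RS08625) rose by 1.60 ± 0.27 and 1.65 ± 0.30.

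Of 8 carotenoid synthesis genes 3 rose and none fell from Mid-P to Low-P (median 0.77, camera adjusted p = 0.0253; adjusted p = 0.192 with an estimated correlation), among them a beta-carotene hydroxylase gene (TX72_RS01460, 1.02 ± 0.15) and a zeta-carotene desaturase gene (TX72_RS11155, 1.04 ± 0.25). Of 5 RNA polymerase core genes 2 fell from High-P to Mid-P (median -0.82, camera adjusted p = 0.0469; adjusted p = 0.406), those of the alpha (-1.32 ± 0.16) and beta subunits (-0.94 ± 0.21). These lists were not refitted under other scalings or without single libraries. The lists of chlorophyll synthesis, translation factors, glycosyltransferases, 2-component regulators, protein secretion and cytochrome b6f passed in none of the comparisons, with camera adjusted p of 0.133 or more.

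Splits of the same libraries were compared with the real groups after the results were seen. For each pair of groups 1 of 10 splits, the real one, gave as many changed genes (705, 302 and 776, with 0 the highest of the others), and 10 splits are too few for a share under 0.05. Across the 3 levels 1 of 100 splits, the real one, gave as many (939, against 418 for the highest other). That share is under 0.05, so random grouping of the libraries is an unlikely source of the count. Splits cannot tell phosphate from a run or culture batch that coincides with treatment.

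The comparison table that the authors deposited held 1058, 595 and 1148 genes past an adjusted p of 0.05 for Low-P versus High-P, Mid-P versus High-P and Low-P versus Mid-P, and DESeq2 on the recovered reads called the same genes. All 705, 302 and 776 limma calls were among them, with the same sign. Their pattern column put 880 genes in a Mid-P peak, 833 in a rise towards Low-P, 322 in a fall towards Low-P, 653 in a complex pattern and 24 in a flat one.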
